A study of Homo sapiens with 12 samples.

How the data were processed

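RNA sequencing libraries were analysed from 12 samples of HepaRG cells, a human hepatoma line whose cultures hold hepatocyte-like and biliary-like cells. The labels give 2 genotypes, wild type (WT) and a knockout of the human constitutive androstane receptor (KO), and 3 treatments: the solvent DMSO, phenobarbital (PB) and the synthetic CAR agonist CITCO. Each of the 6 groups holds 2 libraries. The labels do not say that the duplicates came from separate cultures, so p-values here measure only the spread between these libraries, which may be technical. Doses, exposure times, the way the receptor gene was disrupted, RNA selection and library strandedness are not given in the sources used here. RNA was isolated with a column kit and sequenced with standard Illumina libraries, per the labels' protocols.

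Read alignment and counting were done by the authors. The tools TopHat2 2.0.10, Bowtie 1.0.0, Cufflinks 2.1.1, Cuffdiff 2.1.1 and edgeR 2.12 are named, with no role or order, per the submitters' processing notes, which also name both the current and the preceding human genome assembly. The authors deposited 1 expression table of 15822 loci with gene symbols, whose name calls the values CPM (counts per 1e6 reads). The deposited values are a normalized signal and not plain CPM, because the library totals were 1.07 to 1.11 (WT) and 0.9 to 0.935 (KO) times 1e6, so that the library sizes carry normalization factors. The plan had assumed counts or plain CPM; the values are called CPM here with the meaning just given. In every library 100% of the values were whole multiples, within 0.001 reads, of what 1 read is worth. A general check of that property, which needs many values near 1 read, accepted it for the WT columns and not for the KO columns, which hold too few. Whole reads of the KO libraries therefore rest on the value of 1 read estimated here. They are used for read ratios and for comparing duplicates, and count models were limited to the 6 WT libraries, although the KO values do not rule them out.

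The authors deposited also 7 tables of comparisons with log2 fold changes, p-values and FDR for 14161 loci, all above 1 CPM in at least 8 libraries. They were used only for a check. The authors' deposited table named KO PB against WT PB correlated across loci with r = 0.269 with that comparison computed here and with r = 0.993 with the PB response in KO minus that in WT. For the authors' deposited table named KO CITCO against WT CITCO, r was 0.194 with the named comparison and 0.994 with the difference of the CITCO responses. Loci are not independent replicates. The authors' deposited tables hold 1099 loci under an FDR of 0.05 for WT PB against DMSO, of which 834 were called here, 478 for WT CITCO (275 called here), 1325 for KO PB (942), 319 for KO CITCO (112) and 8295 for KO against WT under DMSO (7832). Those holding the differences of responses have 281 loci for PB, of which 134 were called here, and 187 for CITCO (47).

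The planned test for normalized values was limma on log2(CPM + 0.5), with the spread modelled as a trend on expression, all 12 libraries in 1 fit with 6 group means and 6 residual degrees of freedom. Loci with at least 1 CPM in at least 2 libraries were tested, 15792 of 15822. Calls are Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. Adjusted p-values are limma's unless another tool is named, and fold changes are on the log2(CPM + 0.5) scale, which understates the change of low genes. The 10 comparisons were PB and CITCO against DMSO within each genotype, KO against WT within each treatment, the difference of the PB and of the CITCO response between genotypes, and PB against CITCO in WT cells.

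Lists of genes, the rule for named genes and most alternative settings were fixed before the data were examined. The 23 lists were cytochromes P450 induced through CAR and the pregnane X receptor, AhR targets, phase II conjugation enzymes, hepatic transporters, gluconeogenesis, lipogenesis, fatty acid oxidation, cholesterol synthesis, bile acid synthesis, cell cycle, p53 targets, NRF2 targets, the unfolded protein response, acute phase, interferon response, urea cycle and amino acid catabolism, hepatocyte secreted proteins, liver transcription factors, biliary markers, mesenchymal markers, mitochondrially encoded transcripts, replication-dependent histones and ribosomal proteins. The P450 list also held POR and ALAS1, so that its 13 tested members were not all P450 genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of 89 calls over 9 comparisons, 33 held with the estimated correlation. Further lists for hypoxia, heme synthesis and NADPH supply were written after the data were seen.

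Named genes were the target NR1I3, drug metabolism genes and controls fixed beforehand, up to 8 genes per direction with the largest called change and a mean of at least 5 CPM in 1 group, without overlap of the groups, and up to 4 members per list. Genes outside this rule are said to be chosen after their values were seen. Some genes that meet the rule are not reported here. Reads of near-identical genes can be split between copies, so that values of CYP2B6 and CYP2B7P, CYP3A4 and CYP3A7, CYP2A6, AKR1B10 and AKR1B15, and the GSTA and UGT1A genes carry that uncertainty. Gene positions come from GENCODE 29 on GRCh38 by gene name.

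Alternatives were other pseudocounts (0.1 and 1), no filter and a filter of 5 CPM, a constant prior variance, median-of-ratios scaling, a 2-fold minimum, a fit of only the libraries compared, the replicate number as a block, each library left out in turn, and edgeR's quasi-likelihood test and DESeq2 on the whole reads of the WT libraries. Scaling each library to its total was added after the data were seen, as was median-of-ratios scaling for the lists. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. On data simulated for WT PB against WT DMSO over 15792 loci, limma recovered 70.2% of the 67 genes changed 1.5-fold, 88.1% of the 67 changed 2-fold and 100% of the 66 changed 4-fold, and 9.0% of its calls were false. In the same simulation camera called the raised list (adjusted p = 2.23e-68) and 0 of the other lists. The loci were drawn independently there, so this does not check how camera treats lists of correlated genes.

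Depth was 49.3 to 66.5 times 1e6 reads in the table per library, so that 3 reads correspond to 0.0415 to 0.0669 CPM. Intervals from reads cover counting error only, at 95% confidence. The chi-square of the duplicates' reads was 4.14 to 10.4 per locus, so that no pair of libraries agreed within sampling noise.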

Results

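Transcript levels were compared between WT and KO HepaRG cells under DMSO, PB and CITCO, to ask which drug responses need CAR and what else differs between the genotypes. Genotype was the main source of variance: the first principal component held 84% of it and separated KO from WT libraries, and the second held 4%. Albumin (ALB) alone took 10.6 to 11.8% of the signal in WT and 4.41 to 4.82% in KO libraries, and mitochondrially encoded transcripts took 10.6 to 11.5% and 7.43 to 7.95%. Scaling every library to its total instead of using the deposited values moves the median KO minus WT difference of all loci by 0.247 (DMSO), 0.239 (PB) and 0.233 (CITCO) on the log2 scale. Genotype differences below are relative to the deposited scaling unless the total scaling is named.

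NR1I3, which encodes CAR (chromosome 1, 161229666 to 161238302, minus strand), was transcribed in KO cells at close to the WT level. Means were 11.7 ± 0.36 CPM in WT and 10.8 ± 0.321 CPM in KO cells under DMSO (SD, n = 2), with no called difference (log2 -0.12, adjusted p = 0.273, and 0.14 in the other direction with total scaling). Under PB it was 15.1 ± 0.473 and 15.9 ± 0.469 CPM (log2 0.07, adjusted p = 0.523; with total scaling 0.31, adjusted p = 0.00452). Under CITCO it was 9.51 ± 0.263 and 10.2 ± 0.776 CPM (log2 0.09, adjusted p = 0.388; with total scaling 0.33, adjusted p = 0.00294). The labels give no position of the edit, so a transcript level checks nothing about the genotype. PB raised NR1I3 in KO cells (log2 0.54, adjusted p = 0.000501) and in WT cells (0.36, adjusted p = 0.0181). The WT call was lost without WT DMSO 1 (adjusted p = 0.0946) and without WT PB 2 (0.105), and in a fit of only the libraries compared (0.168). CITCO left it uncalled in WT (-0.29, adjusted p = 0.104) and KO cells (-0.08, adjusted p = 0.819).

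**Figure D1:**
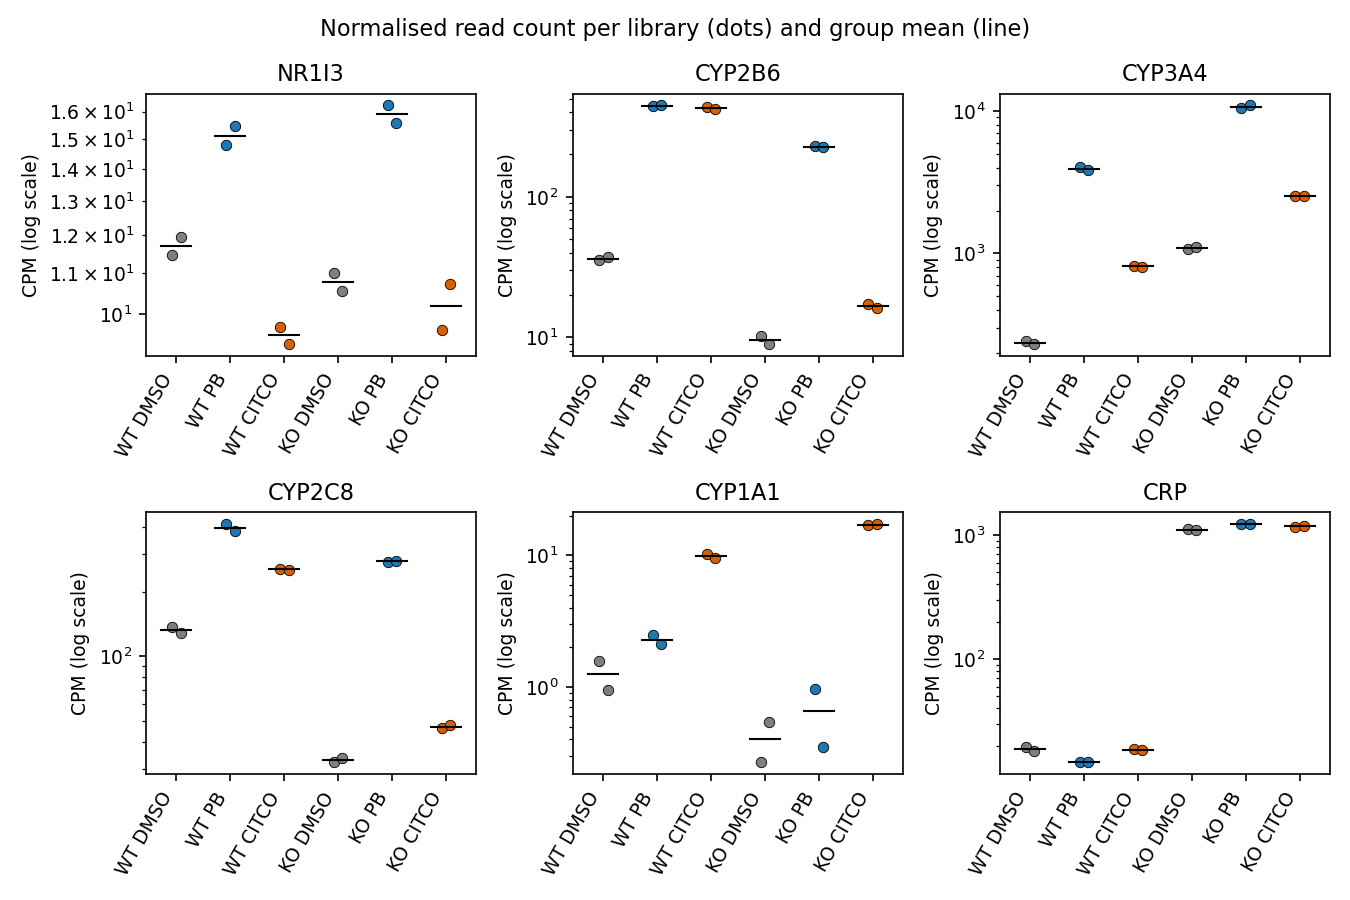
Levels of 6 genes (CPM, log axis) in the 6 groups, where dots are libraries and lines are group means. CYP2B6 rises with PB in both genotypes and with CITCO mainly in WT cells, while CRP is higher in every KO library.

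In WT cells, PB raised the P450 enzymes that oxidise drugs. CYP3A4, the most abundant of them in adult liver, rose 16.6-fold, from 237 to 3928 CPM (log2 4.05, SE 0.035, n = 2, adjusted p = 1.59e-22). CYP2B6, the usual marker of CAR activation (chromosome 19, 40991250 to 41018398), rose 12.2-fold, from 36.1 ± 1.36 to 445 ± 3.39 CPM (log2 3.60, SE 0.058, adjusted p = 4.75e-18). CYP2C8 rose by 1.59, CYP2A6 by 1.37 and CYP3A7 by 2.1 on the log2 scale. With them rose POR (0.92), which passes electrons to every microsomal P450, and ALAS1 (0.45), which makes the first intermediate of their heme. All 13 tested members of the P450 list rose, over all genes and adjusted over the list alone (median log2 1.37, camera adjusted p = 4.05e-39, and adjusted p = 0.000517 with an estimated correlation).

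Other steps of drug handling followed. Of 16 phase II enzymes, 9 rose and 1 fell (11 and 2 adjusted over the list alone; median 0.36, camera adjusted p = 2.31e-08, and 0.04 with an estimated correlation), among them EPHX1 (0.73), which hydrolyses epoxides, the glucuronosyltransferases UGT1A1 (0.49) and UGT2B4 (0.88), and the sulfotransferase SULT2A1 (0.63). Of 11 NRF2 targets, 7 rose, also over the list alone (median 0.36, camera adjusted p = 5.35e-11, and 0.0373 with an estimated correlation), including the aldo-keto reductases AKR1B10 (1.05) and AKR1C2 (0.89), and outside the lists the peroxidase GPX2 rose (1.87). Of 17 transporters, 8 rose and 2 fell (9 and 2 alone; camera adjusted p = 9.92e-05, but adjusted p = 0.0717 with an estimated correlation), with rises of the exporters ABCC2 (0.97), ABCB1 (0.73) and SLC47A1 (0.59). AKR1D1 (1.17), a reductase of bile acid synthesis, and KLB (0.65), the co-receptor for FGF19, rose among the 7 of 16 bile acid genes that did, while 1 fell (8 and 3 alone; camera adjusted p = 0.00187, and 0.04 with an estimated correlation). Cholesterol synthesis rose in 4 of 21 genes (10 alone), and urea cycle and amino acid genes in 6 of 15, with 1 that fell (9 and 1 alone), ARG1 rising by 0.49. These lists were called by camera (adjusted p = 0.00187 and 0.00148, and 0.04 with an estimated correlation for both).

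Among the genes that fell with PB in WT cells were POSTN (-1.30), a matrix protein, IGFBP1 (-1.19) and IGFBP3 (-0.84), which bind insulin-like growth factors, the carbonic anhydrase CA9 (-0.87), the keratin KRT6A (-0.92) and CYP4A11 (-0.70), a fatty acid hydroxylase. Of 19 acute phase genes, 7 fell, also over the list alone, such as CRP (-0.34, adjusted p = 3.74e-05, but 0.159 in a fit of only the libraries compared) and FGB (-0.18, lost there with 0.0871); camera gave adjusted p = 0.00217, but adjusted p = 0.0717 with an estimated correlation. Gluconeogenesis had 4 of 12 genes that fell, G6PC by 0.30, and 1 that rose (5 and 1 alone; camera adjusted p = 0.0142, and adjusted p = 0.0743 with an estimated correlation), while PCK1 was uncalled (-0.14, adjusted p = 0.27). Of the mesenchymal markers, 3 of 11 fell (4 alone; camera adjusted p = 0.0215, and adjusted p = 0.0898 with an estimated correlation), and of the mitochondrial transcripts 2 of 10 rose (4 alone; camera adjusted p = 0.0177, and adjusted p = 0.406 with an estimated correlation). Camera also called interferon response genes and ribosomal proteins (adjusted p = 0.00357 and 0.00148) with 0 members passing limma, and adjusted p = 0.102 for both with an estimated correlation. FBXW10 (1.47) and ANO1 (1.40), a chloride channel, had some of the largest rises outside the lists. PB changed 1014 loci in WT cells, 420 higher and 594 lower, with 2992 at an unadjusted p under 0.05; 26 were at least 2-fold higher and 6 at least 2-fold lower. The count of 1014 was 242 in a fit of only the libraries compared, 537 with a constant prior variance, 554 with edgeR and 663 with DESeq2.

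CITCO in WT cells raised CYP2B6 11.7-fold (log2 3.55, n = 2, adjusted p = 1.21e-17) and, more than PB did, the AhR target CYP1A1. CYP1A1, which oxidises polycyclic hydrocarbons (chromosome 15, 74719542 to 74725610), rose from 1.26 to 9.87 CPM (log2 2.58, SE 0.221, adjusted p = 9.01e-07). CYP3A4 rose 3.43-fold (log2 1.78), CYP2A6 by 1.20, CYP2C8 by 0.94 and POR by 0.55. Of the 13 members of the P450 list 10 rose, and 13 over the list alone (median 0.85, camera adjusted p = 9.42e-31, and 0.000588 with an estimated correlation). NRF2 targets rose in 8 of 11 genes, also alone (median 0.27, camera adjusted p = 2.26e-13, and 0.0117 with an estimated correlation), with AKR1B10 at 1.03, AKR1C2 at 0.85 and SRXN1, which repairs peroxiredoxins, at 0.59. GPX2, outside the lists, rose by 1.68. Of 5 AhR targets 3 rose, also alone, ALDH3A1 by 0.95 (median 0.95, camera adjusted p = 0.000444, and 0.0441 with an estimated correlation). Phase II enzymes rose in 8 of 16 (10 rose and 2 fell alone; camera adjusted p = 2.7e-07, and 0.0375 with an estimated correlation), with UGT2B4 at 0.59, EPHX1 at 0.53 and UGT1A1 at 0.29, and ABCC2 rose by 0.34. ALAS1 (0.15, adjusted p = 0.175) and ABCB1 (0.08, adjusted p = 0.374) were uncalled.

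CITCO also raised cell cycle genes in WT cells: 11 of 26 rose, 22 over the list alone (median 0.29, camera adjusted p = 1.44e-19, and 0.000588 with an estimated correlation), such as cyclin B1 (CCNB1, 0.51) and the proliferation marker MKI67 (0.34). Of 12 gluconeogenesis genes 4 fell (7 alone; camera adjusted p = 3.48e-06, and 0.0117 with an estimated correlation), among them PCK1 (-0.45, adjusted p = 0.000953), which commits carbon to glucose, and G6PC (-0.34), which releases it, and IGFBP1 fell too (-0.62). In a fit of only the libraries compared, the calls of CCNB1 (adjusted p = 0.0802), MKI67 (0.0735), PCK1 (0.059) and IGFBP1 (0.0572) were lost. Acute phase genes fell in 2 of 19 (11 alone; camera adjusted p = 1.76e-05, and 0.0299 with an estimated correlation), and interferon response genes in 2 of 17 (6 alone; camera adjusted p = 2.75e-05, and 0.0441 with an estimated correlation). CYP2E1, which oxidises ethanol, fell by 0.59. Further calls of camera were lost with an estimated correlation: ribosomal proteins (2 of 23 rose, 6 alone), cholesterol synthesis (4 of 21 fell, 8 alone), lipogenesis (2 of 14 fell, 4 alone, SCD by 0.28) and secreted proteins (6 of 21 fell, 8 alone, AHSG by 0.40). Their adjusted p went, in this order, from 2.21e-05 to 0.0524, from 0.0282 to 0.0849, from 0.0145 to 0.0943 and from 0.0054 to 0.155. CITCO changed 348 loci, 187 higher and 161 lower (252 and 102 with total scaling), with 11 at least 2-fold higher and 0 at least 2-fold lower by limma at the adjusted p; 2578 loci had an unadjusted p under 0.05. The count of 348 was 168 without WT DMSO 1, 992 without WT DMSO 2, 109 without WT CITCO 1 and 136 without WT CITCO 2. It was 72 in a fit of only the libraries compared, 96 with a constant prior variance, 137 with edgeR and 221 with DESeq2.

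Compared directly in WT cells, PB and CITCO gave the same CYP2B6 level within error (log2 0.05, 95% interval -0.07 to 0.17, adjusted p = 0.698). PB gave more CYP3A4 (2.27), CYP3A7 (1.25), AKR1D1 (1.15), SLC16A9 (0.91), a monocarboxylate transporter, the antiviral OAS2 (0.78), ABCB1 (0.65), CYP2C8 (0.65), NR1I3 (0.64), CYP7A1 (0.49), which starts bile acid synthesis, POR (0.36), ALAS1 (0.31) and UGT1A1 (0.20). PB gave less CYP1A1 (-1.90), ALPP (-1.19), a placental phosphatase, C1QL1 (-0.99), POSTN (-0.88) and UHRF1 (-0.72), which maintains DNA methylation. The 992 called loci were 419 higher and 573 lower with PB, and 250 and 947 with total scaling; the count was 525 without WT PB 1, 377 without WT CITCO 1 and 394 without WT CITCO 2. It was 437 in a fit of only the libraries compared, 434 with a constant prior variance, 500 with edgeR and 624 with DESeq2.

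In KO cells PB still raised the P450 genes. CYP2B6 rose 22.7-fold, from 9.59 to 228 CPM (log2 4.50, n = 2, adjusted p = 9.78e-20), CYP3A4 9.78-fold, from 1090 to 10670 CPM (log2 3.29), and CYP2C8 8.33-fold (log2 3.06). CYP3A7 rose by 3.54, CYP2B7P by 1.94, CYP2A6 by 1.52, POR by 1.10 and ALAS1 by 1.06. All 13 list members rose (median 1.5, camera adjusted p = 1.09e-42, and 0.0004 with an estimated correlation). Transporters rose in 8 of 17 (12 alone; camera adjusted p = 2.25e-10, and 0.021 with an estimated correlation), with ABCB1 at 1.51 and ABCC2 at 1.16. Phase II enzymes rose in 10 of 16 and fell in 2 (11 and 3 alone; camera adjusted p = 4.15e-08, and 0.0249 with an estimated correlation), with EPHX1 at 0.98, UGT2B4 at 0.90, SULT2A1 at 0.60 and UGT1A1 at 0.58. NRF2 targets rose in 8 of 11 (camera adjusted p = 1.72e-10, and 0.021 with an estimated correlation), with AKR1B10 at 1.35 and AKR1C2 at 1.21. Bile acid genes rose in 7 and fell in 2 of 16 (8 and 3 alone; camera adjusted p = 0.00343, and 0.0343 with an estimated correlation), AKR1D1 rising by 2.05. NR1I2, which encodes the pregnane X receptor, was uncalled with PB in KO (-0.09, adjusted p = 0.545) and in WT cells (0.04, adjusted p = 0.804).

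**Figure D2:**
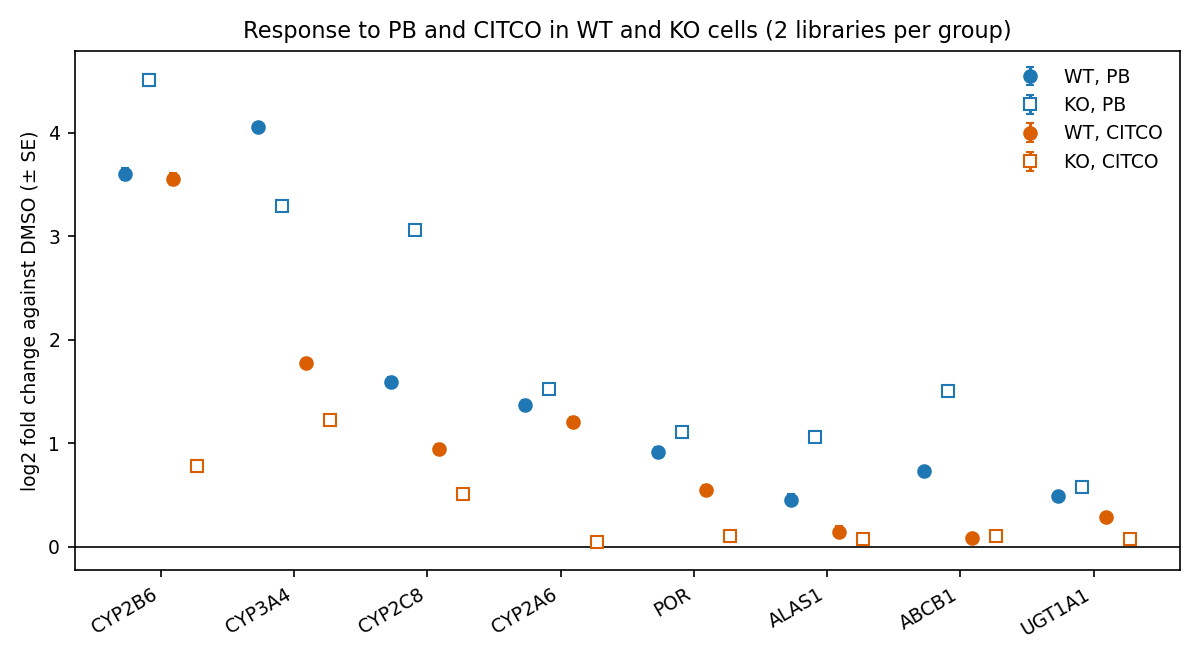
Change with PB (blue) and CITCO (orange) against DMSO (log2, ± SE) of 8 drug metabolism genes in WT (filled circles) and KO cells (open squares). The CITCO response of CYP2B6 is 3.55 in WT and 0.78 in KO cells, and the PB responses are large in both.

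PB in KO cells also raised genes of amino acid metabolism and stress: 8 of 15 urea cycle and amino acid genes rose, also alone (camera adjusted p = 0.000216, and 0.0249 with an estimated correlation), ARG1 by 0.75 and AGXT, which detoxifies glyoxylate, by 0.60. Of 13 genes of the unfolded protein response 5 rose (8 alone; camera adjusted p = 0.000216, and 0.0343 with an estimated correlation), with asparagine synthetase ASNS at 0.64 and its activator ATF4 at 0.34, and the fasting-induced factor CREB3L3 rose by 0.79. Ribosomal proteins rose in 9 of 23 (13 alone; camera adjusted p = 5.01e-06, and 0.0343 with an estimated correlation), and cell cycle genes in 4 of 26 (5 alone; camera adjusted p = 6.27e-05, and 0.021 with an estimated correlation), TOP2A by 0.31. PCK1 rose by 0.43 and FOXN4 by 2.35. Secreted proteins rose in 6 and fell in 1 of 21 (10 and 1 alone; camera adjusted p = 0.00111, but adjusted p = 0.111 with an estimated correlation), with SERPINA1 at 0.27. ORM1, an acute phase protein, rose by 0.22. Among the larger falls were those of the mitochondrial protein NDUFA4L2 (-1.21), HSD3B1 (-1.20) of steroid synthesis, CYP2E1 (-1.03), the monooxygenase FMO5 (-0.86) and the mucin MUC13 (-0.74). G6PC fell by 0.69, SOX4 by 0.59 and CYP4A11 by 0.52.

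Signs of RNA composition moved as well. Of 5 histone genes 1 fell with PB in KO cells and 5 over the list alone (camera adjusted p = 0.000216, and 0.0249 with an estimated correlation), and the 8 near-identical loci of the 5.8S ribosomal RNA RNA5-8S5 fell, the first by 1.25 (adjusted p = 0.000777). These loci, whose reads are shared among copies, were 8 of the 13 that fell at least 2-fold with PB in KO cells. PB changed 1099 loci in KO cells, 611 higher and 488 lower (480 and 707 with total scaling), with 2846 at an unadjusted p under 0.05 and 46 at least 2-fold higher. The count of 1099 was 641 and 671 without KO DMSO 1 and 2, 523 and 532 without KO PB 1 and 2, and 612 with a constant prior variance.

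The PB responses of the genotypes differed at 159 loci, 126 with a higher change in KO cells and 33 with a lower one. The response was larger in KO cells for CYP2C8 (difference 1.47), CYP3A7 (1.44), CYP2B6 (0.90), AKR1D1 (0.87), ABCB1 (0.78) and ALAS1 (0.61), and smaller for CYP3A4 (-0.76), which started 4.6-fold higher in KO cells. It did not pass for CYP2A6 (0.15, adjusted p = 0.481) and POR (0.19, adjusted p = 0.295). In the P450 list 7 members had a larger and 1 a smaller response (9 and 2 alone; median 0.27, camera adjusted p = 9.23e-07, and 0.0328 with an estimated correlation). Of the cell cycle genes 2 changed more upward in KO cells (5 alone; camera adjusted p = 2.77e-05, and 0.0328 with an estimated correlation). FOXN4 (1.89), POSTN (1.02), IGFBP1 (0.81), ABCG8 (0.57), PCK1 (0.57), CREB3L3 (0.51), CRP (0.50) and AHSG (0.48) also had a positive difference. For POSTN and IGFBP1 it is a weaker fall than in WT cells. CRP and AHSG fell in WT cells, while their KO means were higher with PB (1106 to 1228 CPM and 236 to 262.5 CPM). The difference was negative for MUC13 (-0.96), HSD3B1 (-0.93), FMO5 (-0.84) and G6PC (-0.39). Lists called by camera and lost with an estimated correlation were acute phase (5 of 19 more upward in KO cells, with 9 more upward and 1 more downward alone, adjusted p from 8.57e-05 to 0.0604), transporters (4 of 17, with 7 and 1 alone, from 0.00396 to 0.162), secreted proteins (4 more upward and 1 more downward of 21, with 8 and 2 alone, from 0.00396 to 0.162) and mesenchymal markers (2 of 11, 4 alone, from 0.0179 to 0.104). The same held with 0 members passing limma for the unfolded protein response (from 0.00396 to 0.102), cholesterol synthesis (from 0.00396 to 0.0676), histones (from 0.00422 to 0.0809) and interferon response (from 0.0107 to 0.168). RNA5-8S5 differed by -1.47 (adjusted p = 0.0203), a call lost without WT PB 2 (0.0536), KO DMSO 2 (0.142) or KO PB 1 (0.124). The count of 159 was 82 without KO DMSO 2, 66 without KO PB 1 and 71 without KO PB 2. It was 84 in a fit of only the libraries compared. With a constant prior variance it was 25, and the calls of HSD3B1, IGFBP1, CRP, PCK1, G6PC, CREB3L3, AHSG and RNA5-8S5 were lost (adjusted p from 0.0575 to 0.225).

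In KO cells CITCO raised above all CYP1A1, from 0.404 to 17.1 CPM, or 19.7-fold with 0.5 CPM added (log2 4.30, SE 0.221, n = 2, adjusted p = 1.49e-09). The starting level of CYP1A1 lies below the 0.5 CPM added, so this fold understates the change. CYP1A2, the neighbour of CYP1A1, rose by 1.86 (adjusted p = 0.000664) and ALDH3A1 by 1.17, so that 3 of 5 AhR targets rose, also alone (median 1.17, camera adjusted p = 4.64e-09, and 0.01 with an estimated correlation). CYP2B6 rose 1.71-fold (log2 0.78, adjusted p = 4.15e-07), CYP3A4 by 1.22 (adjusted p = 1.76e-13), CYP3A7 by 1.04 and CYP2C8 by 0.51. Of the 13 members of the P450 list 7 rose (9 rose and 1 fell alone, median 0.30, camera adjusted p = 7.99e-12, and 0.00827 with an estimated correlation). CYP2A6 (0.05, adjusted p = 0.799), POR (0.10, adjusted p = 0.412), UGT1A1 (0.08, adjusted p = 0.378) and ABCB1 (0.11, adjusted p = 0.375) were uncalled. Of 26 cell cycle genes 6 rose (19 alone; median 0.25, camera adjusted p = 5.91e-19, and 0.00123 with an estimated correlation), among them CDK1 (0.44, adjusted p = 0.00425), the kinase that starts mitosis, and MKI67 (0.29, adjusted p = 0.00454). CDK1 was uncalled without KO DMSO 1 (0.114) or KO CITCO 2 (0.125), and MKI67 without KO DMSO 2 (0.0863), KO CITCO 1 (0.0613) or KO CITCO 2 (0.116). AKR1C2 (0.35), AKR1B10 (0.31) and ABCC2 (0.28) rose, and the creatine transporter SLC6A8 (-0.44), AKAP12 (-0.41), the lipid droplet protein PLIN2 (-0.26) and the desaturase SCD (-0.21) fell.

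Camera calls lost with an estimated correlation for CITCO in KO cells were NRF2 targets (4 of 11 rose, 5 alone, adjusted p from 6.03e-06 to 0.0904), lipogenesis (2 of 14 fell, 5 alone, from 0.0283 to 0.19), ribosomal proteins (1 alone, from 0.00643 to 0.225) and gluconeogenesis (1 rose and 5 fell alone, from 0.0277 to 0.138). CITCO changed 128 loci in KO cells, 61 higher and 67 lower (85 and 55 with total scaling), with 1743 at an unadjusted p under 0.05. All 8 loci that fell at least 2-fold were copies of RNA5-8S5 (first locus -1.39, adjusted p = 0.00187; 0.0619 without KO DMSO 2 and 0.0729 without KO CITCO 1). The count of 128 was 197 and 200 without WT DMSO 1 and 2, 207 and 209 without WT PB 1 and 2, 44 and 55 without KO DMSO 1 and 2, 84 without either KO PB library, and 40 and 44 without KO CITCO 1 and 2. It was 232 in a fit of only the libraries compared. With a constant prior variance it was 20, and the calls of CYP1A2, CDK1, MKI67, AKR1C2, AKR1B10, ABCC2, PLIN2, SCD and RNA5-8S5 were lost (adjusted p from 0.0565 to 0.185).

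**Figure D3:**
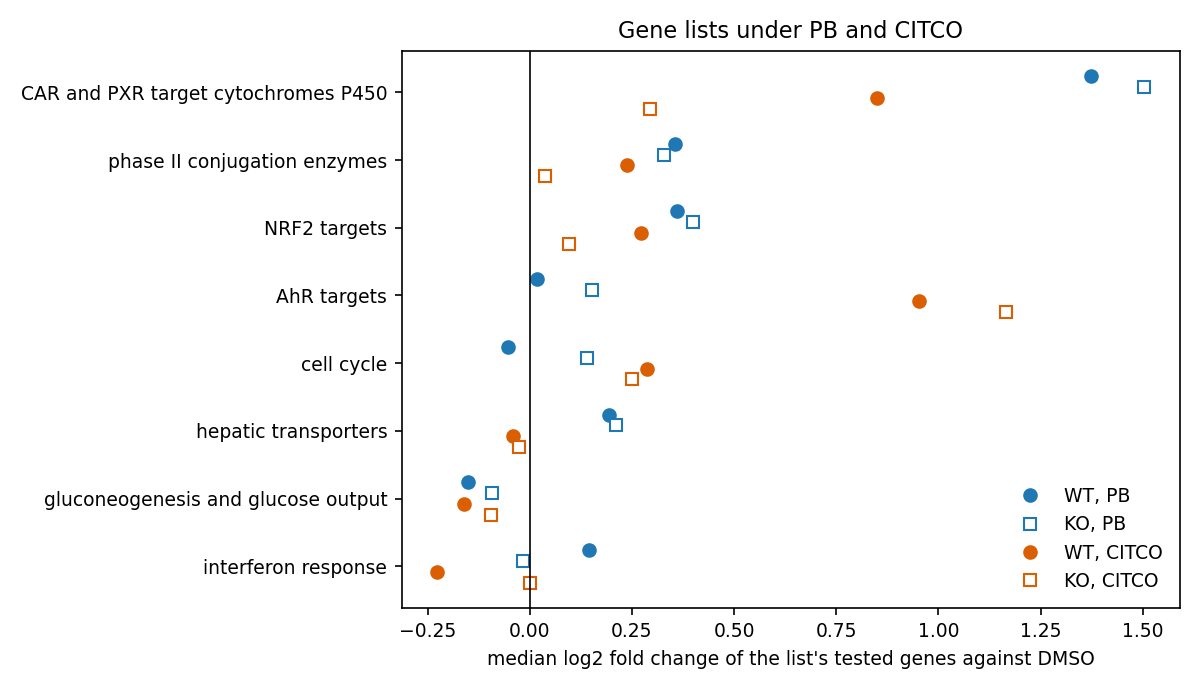
Median log2 change against DMSO of 8 gene lists with PB (blue) and CITCO (orange) in WT (filled circles) and KO cells (open squares). The cell cycle list shifts with CITCO by 0.29 in WT and 0.25 in KO cells.

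The CITCO responses of the genotypes differed at 53 loci, 17 with a higher change in KO cells and 36 with a lower one. Most responses in the P450 list were weaker in KO cells: CYP2B6 by 2.78 (difference -2.78), CYP2B7P (-2.20), CYP2A6 (-1.16), CYP3A4 (-0.55), CYP2C8 (-0.43) and POR (-0.45). The P450 list had 7 members with a weaker response (9 weaker and 1 stronger alone; median -0.43, camera adjusted p = 1.3e-13, and 0.0105 with an estimated correlation). Weaker responses also had GPX2 (-1.41), the NRF2 targets AKR1B10 (-0.72), SRXN1 (-0.52) and AKR1C2 (-0.50) (4 of 11 in the list, 5 alone; camera adjusted p = 9.53e-06, and adjusted p = 0.153 with an estimated correlation), the phase II enzymes UGT2B4 (-0.41) and EPHX1 (-0.33) (2 of 16, with 8 negative and 1 positive alone; camera adjusted p = 0.000143, and adjusted p = 0.153 with an estimated correlation), and the chemokine CXCL13 (-0.61). PCK1 changed more upward in KO cells (0.74). CYP1A1 rose more in KO cells (difference 1.72, adjusted p = 0.0153). The size of this difference depends on the 0.5 CPM added, since the KO DMSO mean of CYP1A1 was 0.404 CPM. In the AhR list 1 of 5 was positive (4 alone, camera adjusted p = 0.0076, and adjusted p = 0.153 with an estimated correlation). The CYP1A1 call was lost without WT DMSO 1 (adjusted p = 0.0581), WT CITCO 1 (0.0818), WT CITCO 2 (0.104), KO DMSO 1 (0.132), KO CITCO 1 (0.0973) or KO CITCO 2 (0.116), and that of CYP2C8 without KO CITCO 1 (0.0514).

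The cell cycle list showed no called difference of the CITCO response (0 genes by limma, camera adjusted p = 0.421). Acute phase (1 of 19, 2 alone; camera adjusted p = 0.0138), interferon response (0 of 17, 4 and 1 alone; 0.0118) and gluconeogenesis (1 of 12, 3 alone; 0.0455) were called and lost, with adjusted p = 0.158, 0.205 and 0.158 with an estimated correlation. RNA5-8S5 differed by -1.79 (adjusted p = 0.00709; 0.0763 without WT CITCO 2, 0.0649 without KO DMSO 2 and 0.0941 without KO CITCO 1) and made up 8 of the 12 loci at least 2-fold lower. The count of 53 was 491 without WT DMSO 2, 103 and 105 without WT PB 1 and 2, 34 and 25 without WT CITCO 1 and 2, 34 without KO DMSO 1, and 23 and 34 without KO CITCO 1 and 2. With a constant prior variance it was 6, and of the genes named for this difference CYP2B6, CYP2B7P, CYP2A6, GPX2 and AKR1B10 were still called, while the others had adjusted p from 0.0583 to 0.191.

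Shared calls put the same contrast in counts. Of the 420 loci raised by PB in WT cells, 234 were also raised in KO cells (16.2 for independent lists) and 91.7% changed in the same direction; the response was weaker in 12 and stronger in 22, and the median went from 0.34 to 0.25. Of the 594 lowered, 234 were also lowered (18.4 for independent lists) and 87.9% changed in the same direction, the fall was weaker in 54 and stronger in 2, and the median went from -0.31 to -0.18. Of the 161 lowered by CITCO, 19 were also lowered (0.683 for independent lists) and 78.3% changed in the same direction, with a weaker fall in 8 and a stronger in 0 by limma, and a median from -0.27 to -0.07. Of the 187 raised by CITCO in WT cells, 29 were also raised in KO cells (0.722 for independent lists) and 79.1% changed in the same direction, the response was weaker in 27 and stronger in 1, and the median went from 0.38 to 0.10. Loci picked by their call in WT cells thus had smaller medians in KO cells in each of these sets. The choice by itself favours this, and the tests of the difference reuse the WT libraries. How much of the drop it explains was not tested. Of the 27 loci with a weaker rise with CITCO in KO cells, 26 were raised by PB in WT cells. Their PB response was weaker in KO cells for 4 and stronger for 6. PB and CITCO raised 97 of the same loci in WT cells and lowered 75, against 4.97 and 6.06 for independent lists. Simulations without drug effects that share the DMSO libraries gave 0.1 and 0.07. They call almost no loci by construction, so they do not measure how far the shared libraries raise the overlap. Across loci the PB and CITCO changes correlated with r = 0.584 in WT cells, against 0.498 in these simulations. In KO cells r was 0.45, against 0.499. The simulated r comes from noise alone, so it does not show how much of the observed r the shared libraries cause. The covariance was 0.0223 in WT and 0.0143 in KO cells, against 0.00717 and 0.00722 in the simulations. In KO cells both drugs raised 39 loci and lowered 44, copies of RNA5-8S5 among the latter (2.36 and 2.07 for independent lists). They moved 1 locus in opposite directions.

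Between KO and WT cells under DMSO, 9106 loci differed, 4462 higher and 4644 lower in KO cells (8291 and 2312 with total scaling), of which 859 and 674 by at least 2-fold. The acute phase protein CRP (chromosome 1, 159712289 to 159714589) was 57-fold higher, 18.9 ± 1.02 CPM in WT and 1106 ± 17 CPM in KO cells (log2 5.83, n = 2, adjusted p = 1.16e-23). The adhesion molecule CADM3 (6.21), PAGE2B (5.79), clotting factor IX F9 (2.16), the stress hormone GDF15 (2.05), CYP3A4 (2.20), CYP8B1 (1.51) of bile acid synthesis and CYP2A6 (0.86) were higher. IGF1, the growth factor, had 8111 reads in KO against 1 read in WT DMSO libraries (ratio 5680, interval 1020 to 225000), and COL6A2 had 7946 against 2 reads (2780, 771 to 23000). EMC10 had 9 reads in the WT libraries (ratio 439, 231 to 961). Lower were CYP2E1 (-3.40), the hormone STC1 (-3.53), MAGEA11 (-3.63), the uptake carriers SLCO1B3 (-2.27) and SLC10A1 (-2.04), CYP2C8 (-1.99), CYP2B6 (-1.86, adjusted p = 8.82e-15), ALB (-1.55), PCK1 (-1.55), CYP7A1 (-1.28), AKR1B10 (-1.59), GSTA1 (-1.66) and ABCB1 (-0.59). NR1I2 was lower (-0.27), but not with total scaling (adjusted p = 0.958).

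Cell cycle genes were higher in KO cells: 23 of 26 were higher and 1 lower (median 0.82, camera adjusted p = 6.49e-07, and 0.0206 with an estimated correlation), with MKI67 at 1.55, CDK1 at 1.25 and TOP2A at 1.17. Of 9 lists called by camera this was the 1 that held with the estimated correlation. Lower but lost with it were transporters (16 of 17 lower, 1 higher, median -0.66, adjusted p from 2.42e-06 to 0.0816), with the sterol exporter ABCG8 at -2.49, phase II enzymes (12 lower, 2 higher of 16, from 0.00125 to 0.13), with UGT2B7 at -1.49 and EPHX1 at -1.22, and liver transcription factors (14 lower, 2 higher of 20, from 0.0029 to 0.0816), with CEBPA at -1.11, HNF4A at -0.87 and PROX1 at -0.71. So were fatty acid oxidation (14 lower, 5 higher of 19, adjusted p from 0.00746 to 0.13), with EHHADH at -1.27, and urea cycle and amino acid genes (11 lower, 3 higher of 15, from 0.00733 to 0.0889), with GLDC at -1.70 and HGD at -1.31. p53 targets were higher (10 higher, 2 lower of 13, with 11 and 2 alone, adjusted p from 0.0079 to 0.0889), with MDM2 at 0.55. The triglyceride enzyme DGAT2 (-1.93), the apolipoproteins APOA1 (-1.79) and APOH (-1.34) were lower, while PLIN2 (1.29) and the bile acid exporter SLC51A (1.99) were higher.

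Markers of other cell types and of RNA composition differed between the genotypes too. Mesenchymal markers were higher in 6 and lower in 2 of 11 (median 0.78, camera adjusted p = 0.0188, and adjusted p = 0.118 with an estimated correlation), with TAGLN at 2.97, DCN at 1.95 and COL6A3 at 3.08. Biliary markers went both ways, 4 higher and 4 lower of 8 (camera adjusted p = 0.75): KRT19 was lower (-2.27), SPP1 (1.27) and SOX4 (1.10) higher. All 10 mitochondrial transcripts were lower (median -0.68, camera adjusted p = 4.87e-05, and adjusted p = 0.285 with an estimated correlation), MT-CYB by 0.88 and MT-CO1 by 0.77. Lists not called were P450 (5 higher, 6 lower, adjusted p = 0.69), acute phase (9 and 6, 0.374), bile acid synthesis (6 and 9, 0.26), secreted proteins (6 and 12, 0.197), NRF2 targets (2 and 6, 0.206), AhR targets (1 and 4, 0.525), gluconeogenesis (5 and 6, 0.525), cholesterol synthesis (5 and 11, 0.206), lipogenesis (4 and 7, 0.242), interferon response (3 and 6, 0.727), the unfolded protein response (5 and 4, 0.755), histones (3 and 0, 0.162) and ribosomal proteins (4 and 11, 0.242). Of these, total scaling reverses the sign of the median for P450, secreted proteins, NRF2 and AhR targets, gluconeogenesis, cholesterol synthesis, lipogenesis, interferon response and ribosomal proteins.

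The genotype difference also followed gene order, a summary chosen after the data were examined. In 200 blocks of 60 neighbouring tested genes, 14 block medians for KO against WT under DMSO lay beyond the farthest of 1000 shuffles of the gene order. The first 120 tested genes of chromosome 8, from ZNF596 to TACC1, had a median of -0.93 relative to all genes, with 113 on the same side. The quartiles were -1.26 to -0.64, and the median was -0.93 under PB and -0.92 under CITCO. With total scaling under DMSO the median of the run itself was -0.66, while that of all loci was 0.247. STC1 lies in that run. IGF1 lies in a block of chromosome 12 with a median of 0.52. CYP2B6 (0.03), CYP3A4 (-0.11) and CRP (0.02) lie in blocks within the shuffles.

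**Figure D4:**
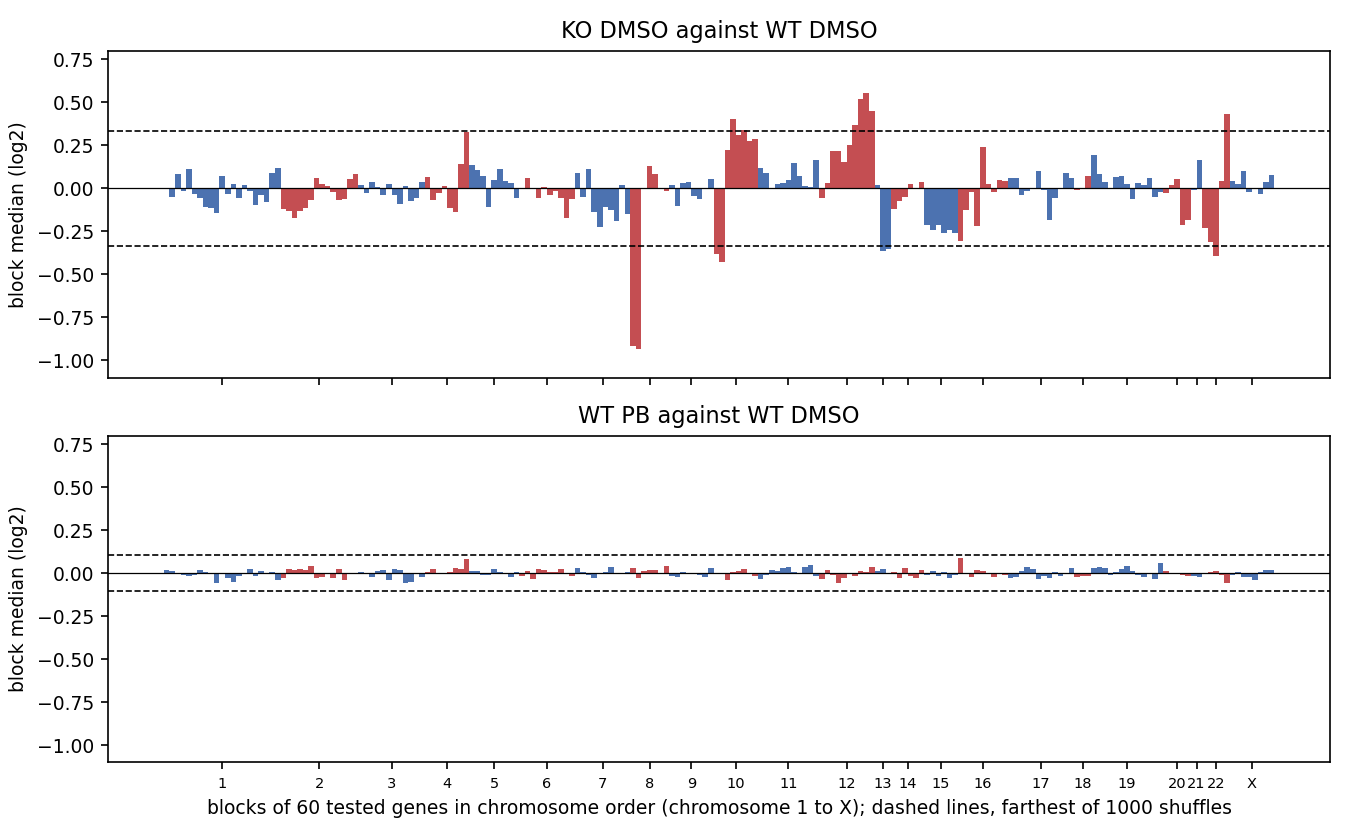
Median log2 difference of blocks of 60 neighbouring tested genes in chromosome order (colours alternate by chromosome), for KO against WT under DMSO (top) and PB against DMSO in WT cells (bottom), with dashed lines at the farthest of 1000 shuffles. A run at the start of chromosome 8 lies near -0.93 in the top panel, and 0 blocks pass in the bottom one.

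Under the drugs the genotype differences were mostly kept, with 3468 loci higher and 3521 lower in KO cells in all 3 treatments. Under PB 9214 loci differed (4646 higher and 4568 lower; 8147 and 2387 with total scaling) and under CITCO 9324 (4622 and 4702; 8090 and 2511). With PB, CYP3A4 (1.44) and CYP2A6 (1.01) were higher in KO cells and CYP2B6 (-0.96) and CYP2C8 (-0.52) lower, while ABCB1 had turned higher (0.18). With CITCO, CYP2B6 was 24.9-fold lower in KO cells (log2 -4.64, adjusted p = 4.37e-20) and CYP2C8 lower by 2.42, with CYP3A4 still higher (1.65). CYP2A6 was lower (-0.29), but not with total scaling (-0.04, adjusted p = 0.47). CRP stayed higher (6.33 with PB, 5.95 with CITCO) and ALB lower (-1.61 and -1.47), as did CYP2E1 (-3.90 and -3.10). ERP27 (-3.48) and LRRC16B (-3.43) were among the lowest under PB, and STC1 (-3.69) and FCGBP (-3.14) under CITCO. Cell cycle genes were higher in 25 of 26 under PB and lower in 1 (camera adjusted p = 1.94e-08, and 0.0121 with an estimated correlation), and in 22 with 1 lower under CITCO (24 and 1 alone; camera adjusted p = 2.35e-06, and 0.0256 with an estimated correlation). The P450 list was called lower under CITCO (10 lower and 3 higher; median -0.34, camera adjusted p = 0.00799, but adjusted p = 0.116 with an estimated correlation).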

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

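All tests weighed in this part were chosen after the results were seen. A test of the difference between the genotypes singled out the following drug responses, which were measured in 2 libraries per group.

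The PB response differed between genotypes at 159 loci. On the log2 scale, the difference KO minus WT was positive for FOXN4 (1.89), CYP2C8 (1.47), CYP3A7 (1.44), POSTN (1.02), CYP2B6 (0.90), AKR1D1 (0.87), IGFBP1 (0.81), ABCB1 (0.78), ALAS1 (0.61), ABCG8 (0.57), PCK1 (0.57), CREB3L3 (0.51), CRP (0.50) and AHSG (0.48). POSTN, IGFBP1, CRP and AHSG fell with PB in WT cells. For POSTN and IGFBP1 the positive difference is a weaker fall in KO cells. The KO means of CRP and AHSG were higher with PB than with DMSO (1106 to 1228 CPM and 236 to 262.5 CPM). The difference was negative for RNA5-8S5 (-1.47), MUC13 (-0.96), HSD3B1 (-0.93), FMO5 (-0.84), CYP3A4 (-0.76) and G6PC (-0.39).

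The CITCO response differed at 53 loci. The difference KO minus WT was negative for CYP2B6 (-2.78), CYP2B7P (-2.20), RNA5-8S5 (-1.79), GPX2 (-1.41), CYP2A6 (-1.16), AKR1B10 (-0.72), CXCL13 (-0.61), CYP3A4 (-0.55), SRXN1 (-0.52), AKR1C2 (-0.50), POR (-0.45), CYP2C8 (-0.43), UGT2B4 (-0.41) and EPHX1 (-0.33). It was positive for CYP1A1 (1.72) and PCK1 (0.74).

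PB raised the P450 genes in KO cells, and 7 of the 13 list members, ALAS1 among them, responded more than in WT cells. CYP3A4 responded less, and the differences of CYP2A6 and POR did not pass. Scaling between libraries is argued against, since a factor per library moves all loci alike, while the median difference of the list lay 0.26 above that of the other loci (camera adjusted p = 0.0328 with an estimated correlation). A lower starting level in KO cells is argued against as the whole cause, since 2 of the 7 members with a larger response were not lower at the start. More NR1I2 transcript in KO cells is argued against, since under PB it was lower than in WT cells (-0.39, SE 0.064, adjusted p = 4.04e-05; -0.14, adjusted p = 0.0546 with total scaling). Whether the pregnane X receptor protein may be more active in KO cells stays open, as neither its protein nor its activity was measured.

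The cell cycle list rose with CITCO in both genotypes, although in KO cells 6 of 26 genes passed and the calls of CDK1 and MKI67 were lost with a constant prior variance. Deeper sequencing of the CITCO libraries is argued against, since in KO cells they held 0.942 of the reads of the DMSO libraries (1.23 in WT cells). The rise in KO cells was measured against their own DMSO libraries (camera adjusted p = 0.00123 with an estimated correlation). A deviation of the WT DMSO libraries therefore cannot account for that rise. The list also rose with PB in KO cells (adjusted p = 0.021), so a deviation of the KO DMSO libraries may add to both. The list was higher in KO CITCO than in KO PB libraries (median 0.11, 1 gene called, unadjusted camera p = 0.00473 with an estimated correlation). Since the duplicates may be technical, these p-values cannot exclude a chance difference between cultures. If no such difference caused the rise, the median of 0.251 in KO cells argues against a need for CAR. A response through another target was not tested.

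A large share of all loci differed between KO and WT cells under DMSO. Scaling between libraries is argued against as the source, since no single factor between the genotypes, from -3 to 3 on the log2 scale, left fewer than the 9106 calls (total scaling gives 10603, 8291 higher and 2312 lower). A lower share of hepatocyte-like cells would raise the markers of every other type if the other cells stayed the same. Of 19 biliary and mesenchymal markers, 6 were lower and 10 higher (4 and 14 with total scaling). The mixed signs argue against a lower share as the only change. A lower share together with a change among the other cells stays open. Loss of CAR cannot be told apart from other differences between the KO and WT cells compared. Of the 27 loci with a weaker CITCO response in KO cells, 13 were lower and 10 higher under DMSO. The lower share was 48.1%, against 29.4% of other loci (Fisher's exact p = 0.054). These loci were picked by a contrast that uses the same DMSO libraries, so this share decides nothing. The labels do not say how many KO lines there were.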

How the results depend on the processing

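Total scaling, the median-of-ratios scaling of the gene list tests and the limit of the count models to WT libraries were chosen after seeing the data. Of 6129 values of named genes under the alternatives, 5924 kept their direction and side of the threshold, 202 became weaker, 2 stronger and 1 reversed. The reversed value is NR1I3 for KO against WT under DMSO, 0.14 with total scaling (adjusted p = 0.171), a difference of the scaling itself.

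A constant prior variance gave 537 loci for PB and 96 for CITCO in WT cells, 612 and 20 in KO cells, 25 and 6 for the differences of the PB and CITCO responses, and 434 for PB against CITCO; the cause was not tested. It ended 32 calls of named genes, those given with the results and FGB with PB (adjusted p = 0.0951), AKR1B15 (0.0519) and SCD (0.0506) with CITCO, and UGT1A1 for PB against CITCO (0.0801), all in WT cells. A minimum of 2-fold left, by construction, 32 and 11 loci in WT cells, 59 and 15 in KO cells, 1533, 1632 and 1518 for KO against WT under DMSO, PB and CITCO, 20 and 14 for the differences, and 14 for PB against CITCO. A fit of only the libraries compared, with fewer samples, gave 242 for PB and 72 for CITCO in WT cells, 232 for CITCO in KO cells, 84 for the PB difference and 437 for PB against CITCO. On the whole reads of the 6 WT libraries, edgeR called 554, 137 and 500 loci for PB, CITCO and PB against CITCO, and DESeq2 663, 221 and 624; the cause was not tested. These tools were not run for the comparisons with KO libraries. Of 89 calls of gene lists, 33 held with the estimated correlation, which widens the error of the lists, 88 with the replicate block, 88 with total scaling and 89 with median-of-ratios scaling.

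With the replicate number as a block the counts were 1003, 367, 1105 and 117 for the drugs, 9126, 9221 and 9338 for the genotypes, 153 and 51 for the differences and 951 for PB against CITCO, and no call of a named gene changed. The differences between duplicates correlated between groups with r from -0.078 to 0.288, above 0.1 in 4 of 15 pairs of groups. Each of these 4 pairs included a DMSO group, and WT DMSO with WT PB was the highest. A batch shared by some libraries is therefore not excluded. The main fit, as planned, did not take the number to pair samples.

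Leaving out each library in turn assumes that a lone library varies like the other groups. It gave 811 to 1102 loci for PB and 109 to 992 for CITCO in WT cells, and 523 to 1298 and 40 to 209 in KO cells. For KO against WT it gave 7888 to 9331 under DMSO, 7692 to 9532 under PB and 7856 to 9610 under CITCO. The differences ranged from 66 to 213 for PB and from 23 to 491 for CITCO, and PB against CITCO from 377 to 1251. Of 3240 values of this kind 22 became weaker.

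Of 270 values of named genes, 253 were called. Some calls rest on the model: the rise of NR1I3 with PB in WT cells missed the threshold with edgeR (adjusted p = 0.0511) and DESeq2 (0.0554), the fall of CRP with edgeR (0.0508), and with only the libraries compared so did CRP (0.159), FGB (0.0871) and, for CITCO, MKI67 (0.0735), CCNB1 (0.0802), PCK1 (0.059) and IGFBP1 (0.0572); the cause was not tested. Depth sets a limit of 0.0415 to 0.0669 CPM for 3 reads.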

Other observations

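The predictions for heme synthesis, NADPH supply and the share of calls outside the shifted blocks were written before their results, and all other tests here were chosen after the results were seen. Genes named in this part were chosen after their values were seen.

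PB lowered genes that low oxygen induces in WT cells: of 28 tested, 18 fell and 2 rose (22 fell over the list alone; median -0.29, camera adjusted p = 7.92e-16; 0.00127 with an estimated correlation). NDUFA4L2 (-1.69), which restrains mitochondrial respiration, the oxygen sensor EGLN3 (-0.73), the glycolytic regulator PFKFB4 (-0.72), NDRG1 (-0.60), lactate dehydrogenase LDHA (-0.42) and phosphoglycerate kinase PGK1 (-0.29) fell, and CA12 rose (0.35). CITCO lowered 13 of the 28 in WT cells (19 alone; median -0.21; adjusted p = 0.00138 with an estimated correlation), with PFKFB4 at -0.53, EGLN3 at -0.42 and NDRG1 at -0.42. In a fit of only the libraries compared, CA12 with PB (adjusted p = 0.106) and PFKFB4 with CITCO (0.156) were uncalled. In KO cells PB lowered 9 and raised 1 (15 fell alone; adjusted p = 0.00696 with an estimated correlation), with PFKFB3 at -0.54 and NDRG1 at -0.28, and CITCO lowered 7 (12 alone; 0.00138). A lower hypoxia response is a candidate explanation. Without CA9, NDUFA4L2, EGLN3 and ANGPTL4, the genes that drew attention to it, the median of the other 24 in WT cells with PB was -0.277 (14 fell and 2 rose; camera adjusted p = 1.69e-11; 0.00284 with an estimated correlation). Oxygen and HIF protein were not measured.

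PB raised genes that supply NADPH, the electron source of POR: 5 of 9 rose in WT cells (median 0.213, camera adjusted p = 0.000157, and 0.0205 with an estimated correlation), with PGD of the pentose phosphate pathway at 0.39 and IDH1 at 0.33. The hypothesis of a joint induction had predicted a rise of this list, but its members were chosen after the data were seen. In KO cells 4 of 9 rose with PB (adjusted p = 0.04 with an estimated correlation), PGD by 0.57 and IDH1 by 0.45. CITCO raised 4 of 9 in WT cells (0.0283), PGD by 0.30, and 0 by limma in KO cells (median 0.03, adjusted p = 0.252 with an estimated correlation). Induction of the whole heme synthesis pathway beside ALAS1 was tested likewise and stays open: with PB in WT cells 2 of 9 other members rose (3 alone), with a median of 0.06 (camera adjusted p = 0.0186; adjusted p = 0.221 with an estimated correlation).

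Runs of neighbouring genes shifted together between KO and WT cells, and a gain or loss of DNA in 1 line may be the source. Chance placement of the changed genes is argued against, since the farthest block median was -0.932 and the farthest in 1000 shuffles 0.333 (permutation p = 0.001, the smallest they can give). The test first planned for this pattern asked for block correlations above 0.9 between treatments and gave r = 0.964 for DMSO with PB and 0.899 for DMSO with CITCO, and it was then replaced by the shuffles. In the run on chromosome 8, 94.2% of the genes shifted the same way, by a median of 1.9-fold, and 107 were called. Further blocks beyond the shuffles lay on chromosomes 12 (4 of 10 blocks, to 0.55), 10 (-0.43 and 0.41), 13 (-0.36) and 22 (-0.39 and 0.43). The shifted blocks as the source of the genotype calls are argued against, since 59.5% of 10992 genes in other blocks were called, against 82.4% of 811 in shifted blocks. By the same measure 0 blocks shifted with PB in WT and KO cells or with CITCO in KO cells, and 3 with CITCO in WT cells, the farthest by 0.189. DNA was not measured, so a copy number change cannot be told apart from a regional change of transcription.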
